A study of Rattus norvegicus with 18 samples.

How the data were processed

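Rings of rat aorta from 3 male Fischer rats aged 5 weeks were kept in culture for 14 days, per the labels' protocols. At day 13 the rings were left untreated, or received recombinant human vascular endothelial growth factor (VEGF, 10 ng/ml) or recombinant human angiopoietin-1 (Ang1, 100 ng/ml) given with a poly-His antibody (5 µg/ml). RNA was taken 20 h after treatment per the sample labels, whereas the series' design text gives 18 h. Each RNA came from 4 to 6 pooled rings of 2 mm. There were 9 RNAs, 3 in each of 3 groups, and each was hybridized to 2 array types, the Affymetrix rat RAE230A (array A) and RAE230B (array B), which makes 18 samples. According to the design text each animal gave 1 RNA to each group, but the labels do not tie the replicate number to the animal. The p-values of single genes therefore measure the spread between these samples, and the main model does not pair them by replicate number. The p-values of gene lists rest mainly on a comparison with other genes, as described below. The labelling of untreated replicate 1 is described as a 2-cycle procedure and that of the other RNAs as the standard one.

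The deposited values are intensities on a linear scale, made with MAS5 per the submitters' processing notes, and the MAS5 version is not given in the sources used here. Per probe set, the deposited value summarises the signal of its probes. The mean signal after trimming 2% at each end was checked on each array. It was 250.0 to 250.1 on 17 of the 18 arrays and 94.8 for Ang1 replicate 3 on array B, which had been scaled otherwise. Detection calls were not used here.

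The analysis used log2(signal + 16). Because the array medians spread over 0.76 log2 units on array A and 1.58 on array B, above the limit of 0.3, arrays of 1 type were quantile normalised. The 57 control probe sets of each array type were left out, and probe sets whose mean lay at or above the 40th percentile were kept, 9520 of 15923 on array A and 9166 of 15333 on array B. Gene symbols came from the platform annotation, matched to current symbols by gene ID. On array A 12789 probe sets had 1 symbol, 312 had several and 2822 were unnamed; on array B the numbers were 7570, 100 and 7663. No gene was named from a probe set with several symbols. The kept probe sets covered 7177 genes on array A and 4035 on array B. Across the 100 probe sets present on both array types, 9 of 9 RNAs matched their own partner array best.

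VEGF against untreated, Ang1 against untreated, and VEGF against Ang1 were tested on each array type with limma 3.58.1 in R 4.3.3, in 1 linear model over the 9 arrays with an intensity trend, followed by Benjamini-Hochberg adjustment within the array type at 0.05. Differences are given in log2 units with the standard error (SE) of the moderated fit, group levels as mean ± SD with n = 3. The number of arrays limits the precision. An exact test of 3 against 3 samples cannot go below p = 0.1, so single genes were tested only within the model over all genes. The model's spread per probe set had a median of 0.44 log2 units on array A and 0.51 on array B.

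Gene lists were tested with camera in limma at a preset correlation of 0.01, with the brightest probe set per gene and adjustment over the lists of 1 comparison and array type. Camera compares the genes of a list with other genes. At the preset correlation its p-value takes little account of spread between arrays that the genes of a list share. Lists could thus be called although the shift was smaller than its SE, as for smooth muscle markers after VEGF on array A. An estimated correlation and fry were run beside the preset correlation. Fry asks whether the genes of a list move on balance one way, and does not compare them with other genes. The 21 pathway lists were chemokines, cytokines and mediators, NF-kB targets, leukocyte adhesion, angiogenic ligands and receptors, tip cell and sprouting, Notch pathway, VEGF early response, FOXO targets, proteases and inhibitors, structural matrix, proliferation, interferon response, complement and acute phase, MHC class II, oxidative stress and metal response, hypoxia and glycolysis, cholesterol synthesis, endoplasmic reticulum (ER) stress and amino acid response, heat shock and ribosomal proteins. The 14 cell type lists were endothelial, smooth muscle, pericyte, fibroblast, macrophage, dendritic, neutrophil, lymphocyte, mast cell, adipocyte, Schwann cell, mesothelial, chondro-osteogenic and erythroid markers. Lists with at least 5 measured genes were tested, 29 on array A and 14 on array B. Neutrophil, lymphocyte, mast cell, mesothelial, chondro-osteogenic and erythroid markers had fewer than 5 on both array types and have no result. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined.

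That rule named, per comparison, the genes past the threshold with all treated values on 1 side of the untreated ones. Fewer than 5 genes qualified everywhere, so the rule's fallback applied, the 8 genes with the smallest unadjusted p in each direction (5 in each for VEGF against Ang1), with the statement that they did not pass. It also named up to 4 members of each list described and 18 fixed genes, of which 16 had a kept probe set. Flt1, a VEGF receptor, and Angpt1, the gene of angiopoietin-1, lay below the filter. Which lists are described at length was decided after their values were seen.

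The replicate numbers come from the sample labels. Whether they pair the samples was checked by correlating the deviations of same-numbered arrays from their group means. Between untreated and Ang1 the 3 correlations were 0.37, 0.49 and 0.34 on array A and 0.14, 0.25 and 0.21 on array B. Between untreated and VEGF they were 0.14, 0.31 and 0.41 on array A and 0.16, 0.22 and 0.29 on array B. All were above 0.1 and highest for the own number, so the numbers were taken to pair these groups. Between VEGF and Ang1 they were 0.23, -0.02 and -0.15 on array A and 0.23, -0.08 and -0.21 on array B, which did not meet that limit. With the replicate number as a block, 294 probe sets differed at an unadjusted p below 0.05 between VEGF and untreated on array A, and 0 passed the adjusted threshold.

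The procedure was tested on simulated data with 200 changed probe sets, in 10 runs per array type, for a simulated VEGF comparison. On array A 8.06% of 2-fold, 79.1% of 4-fold and 96.4% of 8-fold changes were recovered among 9520 probe sets, with 6.7 false calls per run, and on array B 4.33%, 60.7% and 92.7% among 9166, with 5.6 false calls. The chemokine list, raised by 0.5 log2 units, was found in a share of 0.8 of the runs on array A and 0.4 on array B. These simulations drew each probe set independently, with no correlation between genes, no pairing and no arrays that stand apart. The real data differ in this, so the shares and false calls need not hold for them. The alternatives tried were a pseudocount of 1 or 64, no filter or the 60th percentile, values as deposited, median centring, no intensity trend, array weights, only the groups compared, the replicate block, leaving out each array in turn, and the mean of all probe sets per gene. Leaving out untreated replicate 2 and Ang1 replicate 2 together, alone or with the block or an estimated correlation, and scaling all arrays to the same trimmed mean, were added after seeing the data. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.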

Results

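Gene expression was measured in 9 RNAs from cultured rat aortic rings, an explant model in which endothelial sprouts, mural cells, fibroblasts and macrophages grow out of the vessel wall. The 3 untreated, 3 VEGF-treated and 3 Ang1-treated RNAs were each read on array A and on array B. Before quantile normalisation the median log2 signal per array ran from 6.79 to 7.55 on array A and from 6.13 to 7.71 on array B. Of the 9 RNAs, 2 stood apart. Ang1 replicate 2 had a median correlation with the other arrays of 0.69 on array A and 0.43 on array B. Untreated replicate 2 had 0.79 and 0.75, and the other 7 had 0.87 to 0.94 on array A and 0.81 to 0.87 on array B. The deposited signal of the Gapdh 3' probe set, a housekeeping control, was 64.4 in untreated replicate 2 and 446.9 in Ang1 replicate 2 on array A, against 2218 to 3247 in the other 7. On array B it was 309.5 and 542.2, against 3180 to 10980. Both libraries were low by at least 2 log2 units in the same 172 probe sets of array A, where 19.8 would be shared by chance, and in 102 of array B, where 23.4 would be. Among those of array A were the abundant transcripts of Apoe, Bgn, Gpx1, Rplp0 and Eef2. Both libraries were kept, and values without them are given for each list whose call they change. The ratio of 3' to 5' signal of the actin control was 8.79 to 12.4 in VEGF and 1.86 to 7.70 in untreated arrays of type A. On array B it was 5.24 to 11.9 and 3.02 to 5.08. The Gapdh ratios of these groups overlapped, at 9.26 to 15.1 and 1.70 to 11.9 on array A. The lowest untreated ratios on array A, 1.86 and 1.70, were those of untreated replicate 2. In Ang1 replicates 1 and 3 the actin ratio was 8.29 in each on array A and 7.38 and 6.75 on array B, above all untreated arrays. Ang1 replicate 2 had 6.18 and 1.25. The actin ratio was thus higher in the VEGF group and in Ang1 replicates 1 and 3, and no comparison was adjusted for it.

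**Figure D1:**
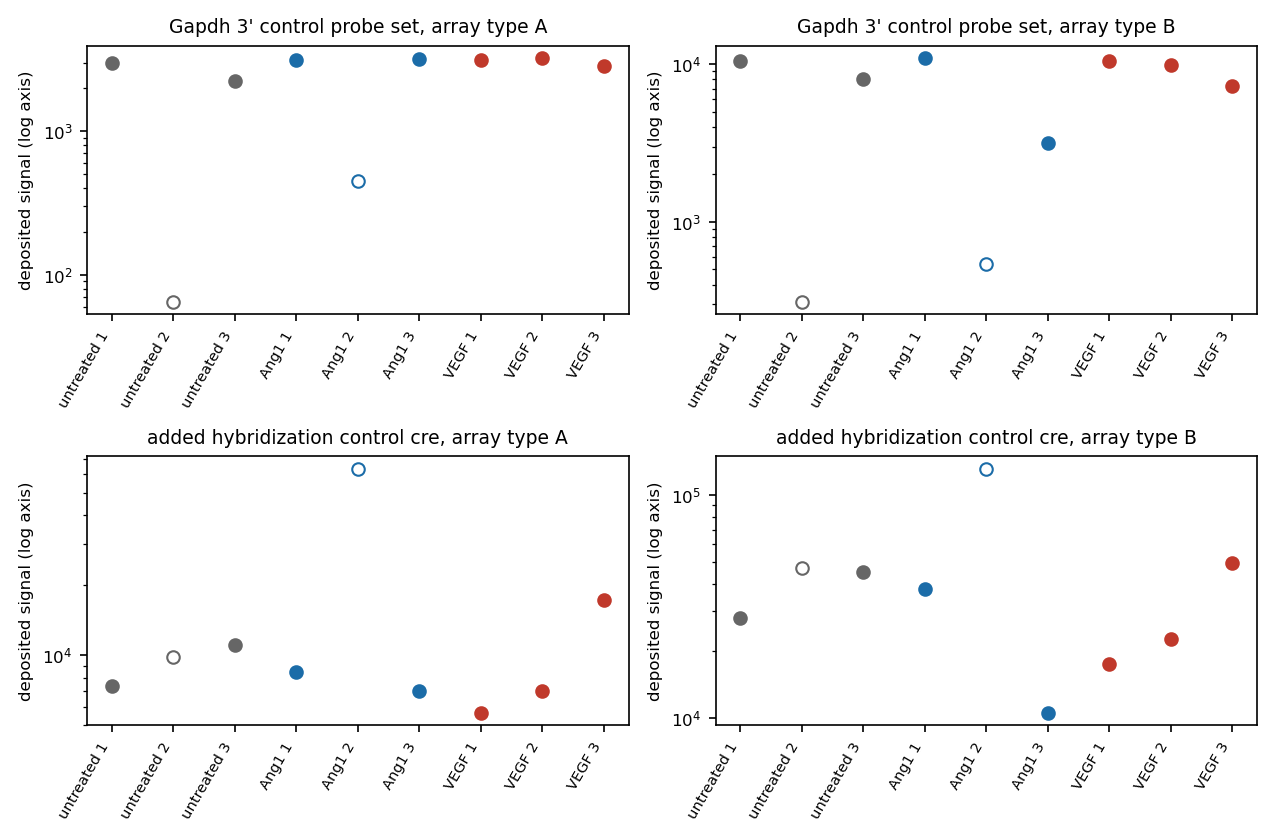
Deposited signal (log axis) of the Gapdh 3' control probe set and of the spiked hybridization control cre on the 9 arrays of each type, with 1 point per array. Untreated replicate 2 and Ang1 replicate 2 have the lowest Gapdh signals on both array types (64.4 and 446.9 on array A), and Ang1 replicate 2 has the highest cre signal (63368.7 on array A, 131371 on array B).

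To ask which transcripts differ in rings exposed to VEGF, the growth factor that drives endothelial sprouting, VEGF-treated rings were compared with untreated ones on array A. Ccm2, a scaffold protein of endothelial junctions (probe set 1375282_at), was 4.66-fold higher (2.22 ± 0.55 log2, SE, n = 3 per group). Emcn, which encodes the endothelial sialomucin endomucin (1372587_at), was 1.88-fold higher, with 7.53 ± 0.06 log2 units after VEGF against 6.63 ± 0.17 in untreated rings (SD, n = 3). The transcription factor gene Junb (1.15 ± 0.40), the gene of interleukin-1 beta, Il1b (0.94 ± 0.33), and the interferon-gamma receptor gene Ifngr2 (0.82 ± 0.29) were higher as well, as were Txndc12 (0.97 ± 0.30), Tom1l2 (0.96 ± 0.35) and Dmwd (0.94 ± 0.33). Pln, which encodes phospholamban, a regulator of the muscle calcium pump (1388876_at), had 0.391 times the untreated level, 7.58 ± 0.30 against 8.94 ± 0.13 log2 units. Fabp3, a fatty acid binding protein gene (-1.24 ± 0.33), Sugt1 (-1.35 ± 0.32), Usp12 (-1.29 ± 0.30), Rpp30 (-1.14 ± 0.30), LOC100910558 (-1.03 ± 0.29), Pigp (-1.02 ± 0.28) and Eci3 (-0.94 ± 0.24) were lower. In each of these 16 genes all 3 VEGF values lay outside the range of the untreated ones. Their choice by small p-values favours this, and the share of 10% that chance gives with 3 against 3 holds only for genes not so chosen. None passed the adjusted threshold (limma, adjusted p = 1.00 for each). The counts of probe sets were 0 at the adjusted threshold and 157 at an unadjusted p below 0.05, 56 higher and 101 lower, where 476 would be expected by chance. That count was 86 without untreated replicate 2, 276 without untreated replicate 3, 369 without Ang1 replicate 2, 303 without both libraries that stood apart, and 294 with the replicate block. Ang1 replicate 2 enters this comparison only through the normalisation and the spread shared by the 9 arrays, so the count depends on these. In no comparison does a count below the chance level show absence of change.

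Among the genes chosen in advance, the monocyte chemokine gene Ccl2 was 1.00 ± 0.44 log2 higher after VEGF and the neutrophil chemokine gene Cxcl1 1.25 ± 0.85 higher (SE, n = 3 per group). The VEGF receptor gene Kdr differed by 0.16 ± 0.41, the orphan receptor gene Tie1 by -0.19 ± 0.29, the angiopoietin gene Angpt2 by 0.27 ± 0.27 and, on array B, the angiopoietin receptor gene Tek by -0.41 ± 0.35. The endothelial adhesion gene Pecam1 differed by 0.55 ± 0.61, Vwf by -0.06 ± 0.46, the smooth muscle actin gene Acta2 by -0.38 ± 0.45, and the macrophage marker Cd68 by -0.01 ± 0.35. For the matrix metalloproteinases the differences were 0.42 ± 0.40 (Mmp2), 0.63 ± 0.63 (Mmp3) and 0.07 ± 0.77 (Mmp9). Vegfa (-0.07 ± 0.32) and Il6 (-0.02 ± 0.45) lay near 0, and with values as deposited these turned to 0.10 and 0.16, and Vwf to 0.07.

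**Figure D2:**
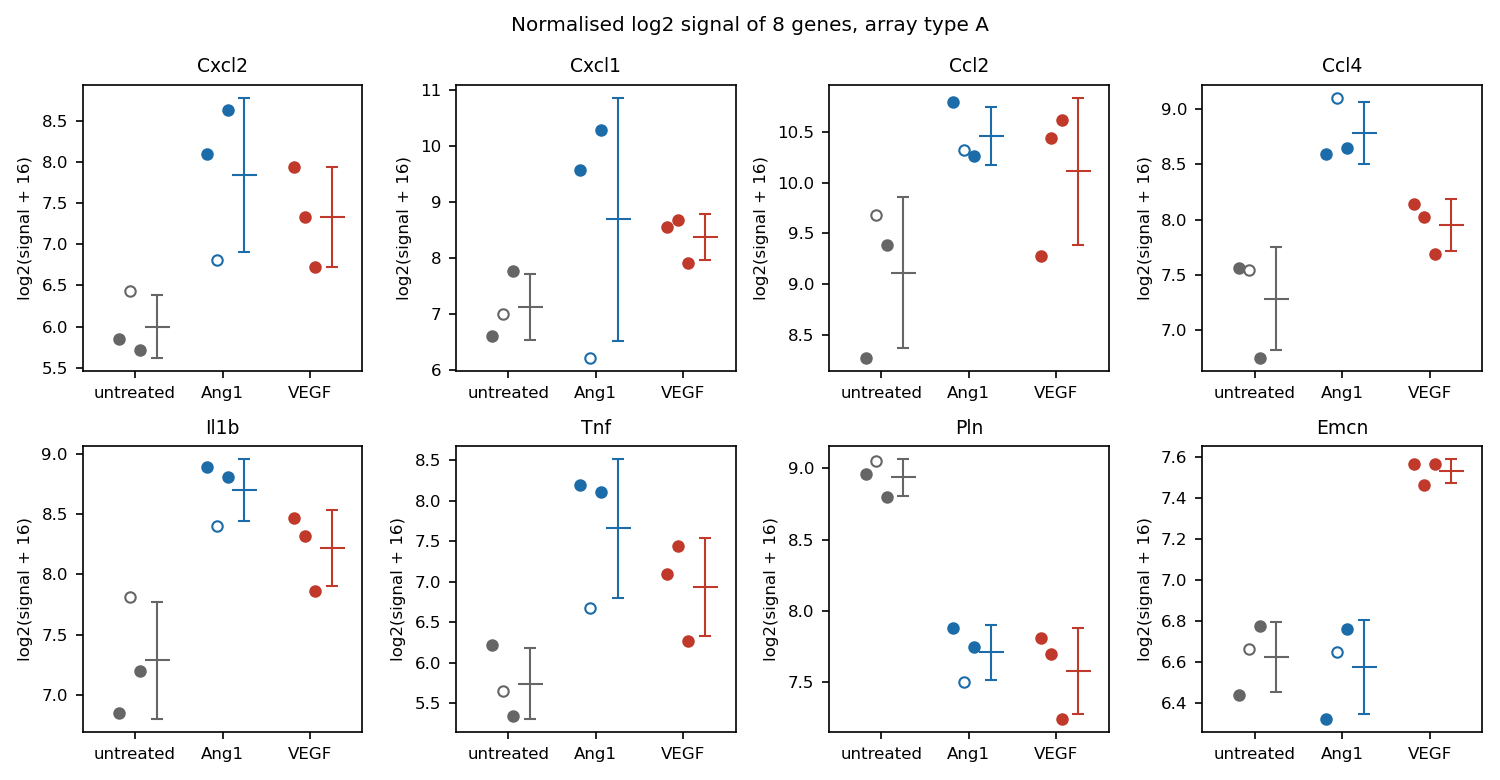
Normalised log2(signal + 16) of 8 genes on array A in the 3 untreated, 3 Ang1 and 3 VEGF arrays, with points for single arrays, horizontal bars for the mean, vertical bars for the SD, and open symbols for untreated replicate 2 and Ang1 replicate 2. The treated arrays of Pln lie between 7.24 and 7.88, below the untreated ones at 8.80 to 9.05, and the Emcn values after VEGF, 7.47 to 7.57, lie above all others.

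Chemokine genes and NF-kB targets were mostly higher after VEGF. Of 14 chemokine genes 13 were higher, by a mean of 0.57 ± 0.22 log2 (SE, camera, adjusted p = 5.24e-05, but adjusted p = 0.20 with an estimated correlation). The list mean of all 3 VEGF arrays lay above all untreated arrays. Cxcl2, a neutrophil chemokine gene, differed by 1.33 ± 0.48, the membrane-bound Cx3cl1 by 0.87 ± 0.36 and Ccl4 by 0.67 ± 0.32, and only the platelet factor gene Pf4 was lower (-0.64). All 15 NF-kB target genes were higher, by a mean of 0.45 ± 0.23 (adjusted p = 5.24e-05, but adjusted p = 0.20 with an estimated correlation, 3 of 3 arrays), among them the interferon regulatory factor gene Irf1 (0.54 ± 0.26), the NF-kB inhibitor gene Tnip1 (0.57 ± 0.32) and the survival genes Birc3 (0.54 ± 0.30) and Cflar (0.57 ± 0.32). Of 15 genes of cytokines and mediators 9 were higher and 6 lower, by a mean of 0.28 ± 0.07 (adjusted p = 0.0379, but adjusted p = 0.287 with an estimated correlation, 3 of 3 arrays), with Tnf at 1.20 ± 0.47 and Il16 at 0.57 ± 0.29. Over all alternatives the adjusted p of these 3 lists ran from 3.2e-13 to 0.442, from 4.16e-06 to 0.442 and from 0.000995 to 0.442. No member of these lists passed over all genes or adjusted over the list alone. The chemokine and NF-kB calls held with each array left out. Untreated replicate 2 had the highest chemokine mean of the untreated arrays. Without both libraries that stood apart, and so without that array, the chemokine mean was 0.83 ± 0.08 with 5 members past the threshold adjusted over the list alone (adjusted p = 0.0459 with an estimated correlation). By contrast, the cytokine call ended without untreated replicate 1 (0.26), untreated replicate 3 (0.27), VEGF replicate 1 (0.26) or VEGF replicate 2 (0.29). The interferon list shares 1 gene with the chemokines (Cxcl10) and 1 with the NF-kB targets (Irf1). The NF-kB list also shares 2 genes each with the leukocyte adhesion and FOXO lists and 1 each with the early response and oxidative stress lists.

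Of 4 further immune lists camera called each higher after VEGF, and with an estimated correlation it called 0 of them. All 6 MHC class II genes were higher (mean 0.45 ± 0.27, adjusted p = 0.00488, but adjusted p = 0.287 with an estimated correlation, 2 of 3 VEGF arrays above all untreated ones), with RT1-Bb at 0.73 ± 0.36 and the invariant chain gene Cd74 at 0.65 ± 0.42. Of 15 complement and acute phase genes 13 were higher (0.42 ± 0.24, adjusted p = 0.00646, but adjusted p = 0.20 with an estimated correlation, 3 of 3 arrays), with C1qb at 0.81 ± 0.37 and C1qa at 1.70 ± 0.96, subunits of the starter of the classical pathway. Of 27 interferon response genes 23 were higher (0.37 ± 0.30, adjusted p = 0.00167, but adjusted p = 0.337 with an estimated correlation, 2 of 3 arrays), with the peptide transporter gene Tap1 at 1.35 ± 0.76 and the immunoproteasome gene Psmb10 at 1.12 ± 0.56. In the other direction, 1 probe set of Stat2 was lower (-0.88 ± 0.40) and its other kept probe set was not (0.24 ± 0.31). Macrophage markers, 15 of 22 higher, shifted by 0.40 ± 0.24 (adjusted p = 0.00488, but adjusted p = 0.401 with an estimated correlation, 1 of 3 arrays), with Coro1a at 1.89 ± 1.01 and Gpnmb at 0.98 ± 0.46. Of these markers 3, C1qa, C1qb and C1qc, also belong to the complement list. Untreated replicate 2 stood at -2.71 (Coro1a), -3.34 (C1qa) and -2.26 log2 units (Tap1) against untreated replicates 1 and 3. The differences of these genes thus rest in large part on that library. Over all alternatives the adjusted p of MHC class II, complement, interferon and macrophage genes ran from 0.00048 to 0.648, from 0.00182 to 0.442, from 5.96e-08 to 0.679 and from 1.94e-07 to 0.996. No member passed over all genes or adjusted over the list alone. Without untreated replicate 3, which had the lowest macrophage and interferon means of the 9 arrays (-0.70 each), the shifts were 0.24 for MHC class II, 0.10 for interferon and 0.15 for macrophage genes and these calls ended. Without VEGF replicate 1 the MHC class II (0.34) and interferon (0.27) calls ended, without VEGF replicate 3 the interferon shift was 0.57, without untreated replicate 1 the macrophage shift was 0.60, and without untreated replicate 2 the complement shift was 0.24. The complement (0.43) and macrophage (0.39) calls ended with values as deposited. The complement means of untreated replicate 2 (-0.57) and Ang1 replicate 2 (-0.41) were the lowest of the 9 arrays.

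Among vessel wall markers, only the smooth muscle list was called lower after VEGF by camera. Of its 18 genes 13 were lower and 5 higher (mean -0.24 ± 0.30, median -0.33, adjusted p = 0.00488, but adjusted p = 0.287 with an estimated correlation). Pln, the tropomyosin gene Tpm2 (-0.74 ± 0.29), the smooth muscle myosin gene Myh11 (-0.70 ± 0.39) and the calponin gene Cnn1 (-0.50 ± 0.31) had the smallest p-values. Over all alternatives its adjusted p ran from 3.37e-13 to 0.654. Over all genes 0 members passed, and 1, Pln, passed adjusted over the list alone. No VEGF array lay below all untreated ones, because untreated replicate 2 had the lowest mean (-0.46) and untreated replicates 1 and 3 the highest (0.43 and 0.47). The shift was -0.54 without untreated replicate 2, and it was no longer called without untreated replicate 1 (-0.10), untreated replicate 3 (-0.07) or VEGF replicate 3 (-0.15). The 15 endothelial markers shifted by 0.17 ± 0.36 and were not called (adjusted p = 0.387), with the transcription factor gene Erg at 0.72 ± 0.50, and untreated replicate 2 (-0.62) and Ang1 replicate 2 (-0.68) had the lowest endothelial means. Without untreated replicate 2 the endothelial shift turned to -0.13 and the pericyte shift, 0.07 with all arrays, to -0.06, and the latter was -0.01 without VEGF replicate 3.

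The other lists called after VEGF concerned sprouting and metabolism. Of 17 tip cell and sprouting genes 13 were higher (0.32 ± 0.22, adjusted p = 0.0346, but adjusted p = 0.287 with an estimated correlation), with the apelin gene Apln at 0.75 ± 0.35, the membrane protease gene Mmp14 at 1.19 ± 0.81 and the laminin gene Lamc1 at 0.73 ± 0.46. Of these 17 genes 7 also belong to the structural matrix list. Of 27 genes of ER stress and amino acid response 22 were higher (0.28 ± 0.29, adjusted p = 0.00642, but adjusted p = 0.445 with an estimated correlation), with the serine synthesis gene Phgdh at 0.69 ± 0.43 and the asparagine synthetase gene Asns at 0.45 ± 0.28. Of 28 hypoxia and glycolysis genes 17 were higher (0.21 ± 0.20, adjusted p = 0.0346, but adjusted p = 0.445 with an estimated correlation), with the glycolytic genes Tpi1 at 1.09 ± 0.47 and Pfkl at 0.72 ± 0.33 and the glucose transporter gene Slc2a1 at 0.53 ± 0.28. On these lists 1, 2 and 2 of the 3 VEGF arrays lay above all untreated ones. Over all alternatives the adjusted p of sprouting, ER stress and hypoxia genes ran from 0.00133 to 0.679, from 0.00129 to 0.727 and from 0.000416 to 0.679. No member passed over all genes or adjusted over the list alone. With values as deposited the 3 calls ended, at 0.30 for sprouting, 0.28 for ER stress and 0.23 for hypoxia genes. Single arrays also ended them, as the sprouting shift was 0.31 without untreated replicate 1, 0.42 without untreated replicate 3 and 0.18 without VEGF replicate 3, and the ER stress shift 0.08 without untreated replicate 2 and 0.22 without VEGF replicate 1. The hypoxia shift was 0.18 without untreated replicate 1, 0.28 without untreated replicate 3, 0.21 without VEGF replicate 1 and 0.13 without VEGF replicate 3. The ER stress means of untreated replicate 2 (-0.52) and Ang1 replicate 2 (-0.61) lay below those of the other 7 arrays (-0.02 to 0.29), and without both the shift was 0.08 and not called. Proteases and inhibitors, with a mean shift of 0.26, were not called (adjusted p = 0.0793) but were with the replicate block (adjusted p = 0.0152; 0.0129 to 0.718 over all alternatives) and without untreated replicate 3 (0.39), and shifted by 0.15 without untreated replicate 2.

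**Figure D3:**
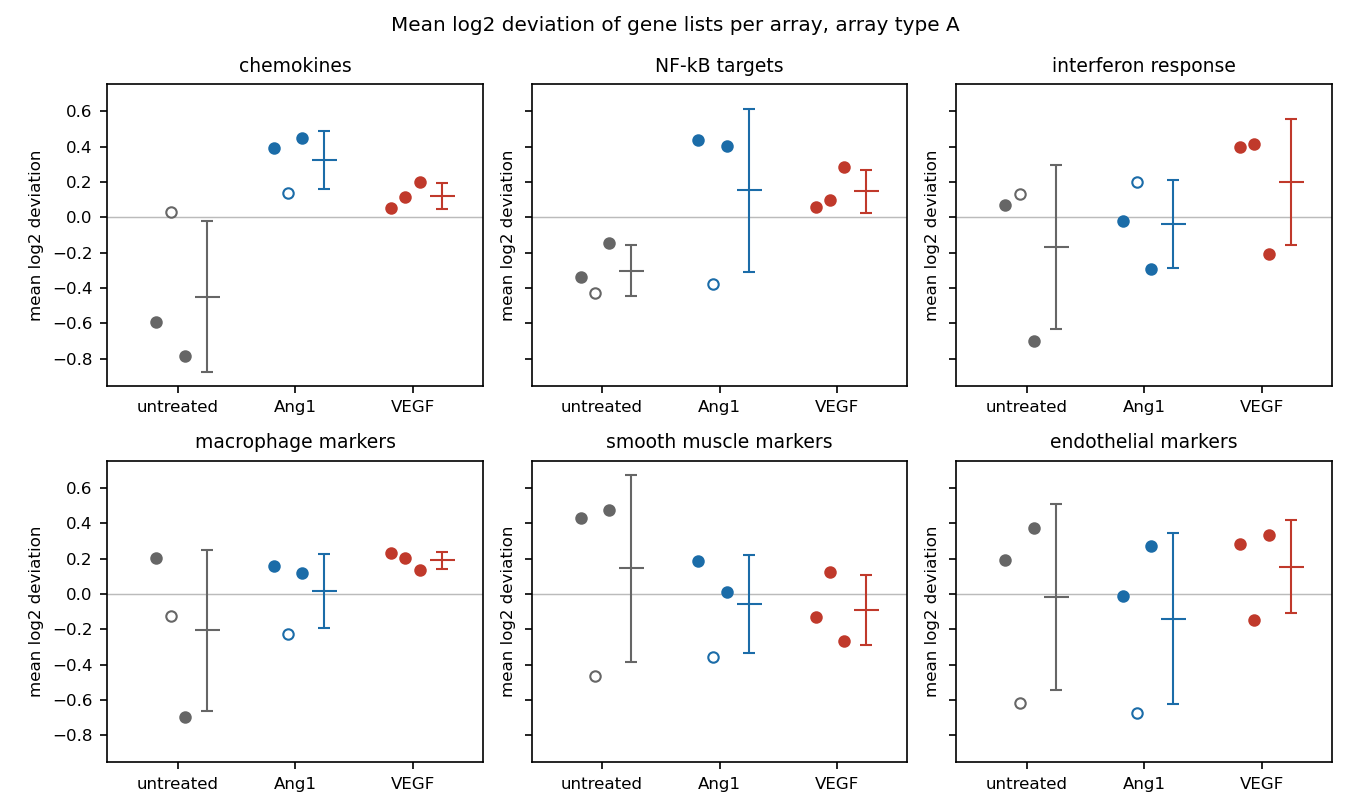
Mean log2 deviation of the genes of 6 lists from their mean over the 9 arrays of type A, with points for single arrays, horizontal bars for the mean, vertical bars for the SD (n = 3), and open symbols for untreated replicate 2 and Ang1 replicate 2. The chemokine means of the 3 VEGF arrays (0.05 to 0.20) and of the 3 Ang1 arrays (0.14 to 0.45) lie above those of all untreated arrays (-0.79 to 0.03).

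On array B, which holds mostly less well characterised transcripts, the VEGF response was sought with the same test. Cybb, a subunit of the phagocyte NADPH oxidase, was 2.00-fold higher (1.00 ± 0.35 log2, SE, n = 3 per group), Slfn2 1.86-fold higher (0.90 ± 0.27), and Etv4, an ETS transcription factor gene, 3.30-fold higher (1.72 ± 0.61). Slc31a2 (1.32 ± 0.50), Poldip2 (1.07 ± 0.40), Camk2g (1.06 ± 0.39), Rxrg (0.89 ± 0.33) and Pilrbl1 (0.82 ± 0.29) were higher. Lrfn4 (-1.10 ± 0.43), Tent4a (-0.99 ± 0.40), Rundc3a (-0.91 ± 0.31), Robo2 (-0.90 ± 0.36, with another probe set in the opposite direction), Spaca9 (-0.89 ± 0.38), Nbeal2 (-0.75 ± 0.34), Stard6 (-0.74 ± 0.31) and Plac9 (-0.68 ± 0.30) were lower. None passed (limma, adjusted p = 0.999 for each). The count was 0 at the adjusted threshold and 66 at an unadjusted p below 0.05, 35 higher and 31 lower, against 458.3 expected by chance. That count was 115 without untreated replicate 1, 42 without untreated replicate 2, 106 without untreated replicate 3, 161 without Ang1 replicate 2 and 131 without both libraries that stood apart. By camera 0 of 14 lists were called, with 3 at an unadjusted p below 0.05 and 0 by fry or with an estimated correlation. The VEGF early response list shifted by 0.40 (adjusted p = 0.123), chemokines by 0.42 (0.129), macrophage markers by 0.33 (0.129) and smooth muscle markers by -0.24 (0.209, 3 of 3 VEGF arrays below all untreated ones). Without untreated replicate 2 the chemokine (0.55), interferon (0.49) and macrophage (0.36) lists were called, and without Ang1 replicate 2 the macrophage (0.34) and early response (0.41) lists. Without both libraries the chemokine (0.59), interferon (0.52) and macrophage (0.37) lists were called, and 0 lists with an estimated correlation. The endothelial shift, 0.14 with all arrays, turned to -0.06 without untreated replicate 2.

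Angiopoietin-1 acts on the Tie2 receptor of endothelial cells, and Ang1-treated rings were compared with untreated ones to ask which transcripts differ with it. Of the 8 higher genes with the smallest p-values, 4 were cytokine or chemokine genes. Tnf, the gene of tumour necrosis factor (1391384_at), was 3.79-fold higher (1.92 ± 0.47 log2, SE, n = 3 per group), Cxcl2 (1368760_at) 3.59-fold higher (1.84 ± 0.48), Ccl4 (1370832_at) 2.82-fold higher (8.78 ± 0.28 against 7.28 ± 0.46 log2 units, SD, n = 3) and Il1b (1398256_at) 2.67-fold higher (8.70 ± 0.26 against 7.28 ± 0.49). Zfp36, whose product speeds the decay of cytokine messengers, was 1.14 ± 0.30 higher, and Ier5 (1.26 ± 0.37), Dpp9 (1.09 ± 0.32) and Cndp2 (1.08 ± 0.29) were higher as well. Pln was lower here too (-1.23 ± 0.27, 0.427 times the untreated level), as were Sugt1 (-1.42 ± 0.32), Fabp3 (-1.15 ± 0.33) and Eci3 (-0.98 ± 0.24). Both comparisons use the same untreated RNAs, so this likeness to the VEGF result is not independent. Spc24, a kinetochore gene (-1.78 ± 0.41), Stat2 (-1.71 ± 0.40, with another probe set in the opposite direction), Lmcd1 (-1.26 ± 0.34) and Thoc1 (-0.93 ± 0.27) were also lower. In all 16 genes, chosen in the same way, the 3 Ang1 values lay outside the range of the untreated ones, and none passed the adjusted threshold (limma, adjusted p = 0.953 for each). The count was 0 at the adjusted threshold and 302 at an unadjusted p below 0.05, 103 higher and 199 lower, against 476 expected by chance. It was 193 without untreated replicate 2, 580 without Ang1 replicate 3 and 296 without both libraries that stood apart. With array weights 6 genes passed, namely Il1b (1.78), Tnf (2.35), Cxcl2 (2.32), Cxcl1 (2.52), Ccl3 (1.79) and Sod2 (1.81), all of them higher. Array weights are estimated from the same arrays and count deviating arrays less. Calls made with them, here and below, are therefore not independent support.

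Of the genes chosen in advance, Ccl2 was 2.55-fold higher after Ang1 (1.35 ± 0.44 log2, SE, n = 3 per group). Cxcl1 differed by 1.57 ± 0.85, with 9.58 and 10.3 log2 units in Ang1 replicates 1 and 3 and 6.22 in Ang1 replicate 2, which stood below all untreated arrays. Il6 differed by 0.07 ± 0.45. Differences of the endothelial genes were -0.46 ± 0.41 (Kdr), 0.30 ± 0.29 (Tie1), -0.22 ± 0.27 (Angpt2), 0.49 ± 0.61 (Pecam1), -0.91 ± 0.46 (Vwf) and, on array B, -0.74 ± 0.35 (Tek). Those of Vegfa, Mmp3 and Mmp9 were 0.37 ± 0.32, 1.15 ± 0.63 and 0.24 ± 0.77. Acta2 (-0.14 ± 0.45) turned to 0.12 with values as deposited, and Cd68 (0.07 ± 0.35) and Mmp2 (0.39 ± 0.40) turned to -0.34 and -0.10 with median centring.

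Of the 14 chemokine genes 13 were higher after Ang1, by a mean of 0.77 ± 0.22 log2 (SE, camera, adjusted p = 4.27e-07, but adjusted p = 0.138 with an estimated correlation), and all 3 Ang1 arrays lay above all untreated ones. Ccl4, Cxcl2, Ccl2 and Ccl3, a macrophage chemokine gene (1.24 ± 0.39), passed adjusted over the list alone, and 0 members passed over all genes. Of 15 cytokines and mediators 12 were higher (mean 0.38 ± 0.07, median 0.11, adjusted p = 0.00429, but adjusted p = 0.138 with an estimated correlation, 3 of 3 arrays), and 2, Il1b and Tnf, passed adjusted over the list alone, with Il1a at 0.91 ± 0.30 and the macrophage growth factor gene Csf1 at 0.69 ± 0.37. Of 15 NF-kB targets 13 were higher (0.45 ± 0.23, adjusted p = 9.15e-05, but adjusted p = 0.222 with an estimated correlation, 2 of 3 arrays), with Irf1 at 0.88 ± 0.26, Birc3 at 0.74 ± 0.30 and the NF-kB subunit gene Relb at 0.71 ± 0.37, and 0 passed adjusted over the list alone. For chemokines, cytokines and NF-kB targets the adjusted p over all alternatives ran from 2.08e-17 to 0.138, from 3.48e-05 to 0.138 and from 1.13e-10 to 0.352. These 3 calls held with each array left out, and the NF-kB shift was 0.74 without Ang1 replicate 2, whose NF-kB mean (-0.38) and that of untreated replicate 2 (-0.43) were the lowest of the 9 arrays. Without both libraries that stood apart the chemokine mean was 1.13 ± 0.09 with 7 members past the threshold adjusted over the list alone (adjusted p = 0.0317 with an estimated correlation). That fit lacked untreated replicate 2, the untreated array highest in chemokines.

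A pair of further lists passed in this comparison. All 6 MHC class II genes were higher (0.46 ± 0.27, adjusted p = 0.00777, but adjusted p = 0.415 with an estimated correlation, 2 of 3 arrays), with RT1-DMa at 0.73 ± 0.31 and the transactivator gene Ciita at 0.64 ± 0.35. Of 21 oxidative stress and metal response genes 13 were higher (0.25 ± 0.20, adjusted p = 0.0474, but adjusted p = 0.415 with an estimated correlation, 2 of 3 arrays), with the superoxide dismutase gene Sod2 at 1.25 ± 0.55 and the heme oxygenase gene Hmox1 at 0.90 ± 0.41. The adjusted p of both lists over all alternatives ran from 0.00176 to 0.494 and from 0.00386 to 0.583, and 0 members passed over all genes or adjusted over the list alone. The MHC class II call ended without untreated replicate 3 (0.25), without Ang1 replicate 2 (0.29) and without both libraries that stood apart (0.33). The oxidative stress call ended without untreated replicate 1 (0.27), untreated replicate 2 (0.09), Ang1 replicate 1 (0.19), Ang1 replicate 3 (0.13) or VEGF replicate 3 (0.25), and with values as deposited (0.28). The shift was 0.42 without Ang1 replicate 2. Untreated replicate 2 (-0.45) and Ang1 replicate 2 (-0.24) had the lowest means of this list.

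Several lists missed the threshold by a margin that a single array decided. Macrophage markers shifted by 0.22 after Ang1 (adjusted p = 0.0902; 0.0334 with the replicate block, 3.49e-05 to 0.986 over all alternatives), with Cybb at 0.71 ± 0.35 and Cd14 at 1.08 ± 0.63. Their shift was -0.02 without untreated replicate 3, and they were called without untreated replicate 1 (0.43), untreated replicate 2 (0.26) or Ang1 replicate 2 (0.35). Proliferation genes shifted by -0.22 ± 0.07 (adjusted p = 0.0932, 3 of 3 Ang1 arrays below all untreated ones), with Racgap1 at -1.23 ± 0.44 and the DNA polymerase gene Pola1 at -0.94 ± 0.46, and were called without untreated replicate 3 (-0.28) or Ang1 replicate 2 (-0.22). Smooth muscle markers shifted by -0.20 (adjusted p = 0.306), with 1 member, Pln, past the threshold adjusted over the list alone and 0 over all genes, and were called without untreated replicate 2 (-0.50). Interferon response genes shifted by 0.13 (adjusted p = 0.171), with 1 member, Stat2, lower adjusted over the list alone, and were called without untreated replicate 1 (0.24), untreated replicate 2 (0.27) or Ang1 replicate 3 (0.25). Endothelial markers shifted by -0.12 (adjusted p = 0.813; 0.10 with values as deposited), with Vwf lowest in Ang1 replicate 2, and the shift turned to 0.15 without Ang1 replicate 2 and to 0.07 without untreated replicate 3, and was -0.42 without untreated replicate 2. The smooth muscle shift was -0.04 and the interferon shift 0.005 without Ang1 replicate 2, and the interferon shift turned to -0.14 without untreated replicate 3. Without both libraries that stood apart macrophage (0.39), proliferation (-0.19) and smooth muscle genes (-0.35) were called, and none of these with an estimated correlation.

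On array B the Ang1 comparison held the largest count of all 6 at an unadjusted p below 0.05. Wfdc2, a secreted protease inhibitor gene (1390765_at), had 0.18 times the untreated level (6.24 ± 0.36 against 8.72 ± 0.31 log2 units, SD, n = 3, limma, adjusted p = 0.107), and the dipeptidase gene Dpep2 (1380512_at) 0.248 times (-2.01 ± 0.32, SE). Smim1 (-2.01 ± 0.35), Afg2b (-2.03 ± 0.37), the mitochondrial genes Hars2 (-2.17 ± 0.40) and Mrpl47 (-1.91 ± 0.38), the ephrin receptor gene Ephb1 (-2.21 ± 0.47) and C5h1orf50 (-1.89 ± 0.42) were also lower. The MHC class II gene RT1-Ba was 3.88-fold higher (1.95 ± 0.49), the chemokine gene Ccl19 2.80-fold higher (1.48 ± 0.35) and the acute phase gene Saa3 2.26-fold higher (1.17 ± 0.33), along with Tesmin (1.92 ± 0.47), Mir9-3hg (1.63 ± 0.40), Tmc4 (1.47 ± 0.43), Nos1ap (1.46 ± 0.43) and Snrnp200 (0.99 ± 0.27). All 3 Ang1 values of these 16 genes, again chosen by small p-values, lay outside the untreated range, and the adjusted p ran from 0.107 to 0.466, so none passed. The count was 0 at the adjusted threshold and 960 at an unadjusted p below 0.05, 406 higher and 554 lower. By chance 458.3 would be expected. The count was 591 without untreated replicate 2, 623 without untreated replicate 3, 1694 without Ang1 replicate 3 and 514 without both libraries that stood apart. With values as deposited, where the median of all probe sets lay at -0.29 and Ang1 replicate 3 had been scaled otherwise, 117 probe sets passed, all of them lower. By camera 0 of 14 lists were called, 0 at an unadjusted p below 0.05 and 0 by fry or with an estimated correlation. Endothelial markers shifted by -0.62 ± 0.52 (0 of 7 higher, adjusted p = 0.537), with Ang1 replicate 2 at -1.64 and the other 8 arrays between -0.25 and 0.55, and the shift was -0.04 without Ang1 replicate 2. Chemokines shifted by 0.47 (adjusted p = 0.537), with 1 member, Ccl19, past the threshold adjusted over the list alone, and proliferation genes by -0.37 (adjusted p = 0.537, 3 of 3 Ang1 arrays below all untreated ones), with the cyclin gene Ccna2 at -1.07 ± 0.38 and the kinase gene Ttk at -1.80 ± 0.54. Structural matrix genes shifted by -0.26 (adjusted p = 0.782), with 1 member, the crosslinking enzyme gene Loxl2 (-1.28 ± 0.31), past the threshold adjusted over the list alone. Without both libraries that stood apart chemokines (0.78), NF-kB targets (0.57) and macrophage markers (0.41) were called, and 0 lists with an estimated correlation.

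VEGF and Ang1 were then compared with each other, to see where the responses to these factors differ. On array A Spc24 was 3.29-fold higher after VEGF than after Ang1 (1.72 ± 0.41 log2, SE, n = 3 per group), and Emcn 1.94-fold higher (7.53 ± 0.06 against 6.58 ± 0.23 log2 units, SD). The glucose transporter gene Slc2a8 (1.78 ± 0.57), the clock gene Per1 (1.24 ± 0.38) and Marf1 (0.97 ± 0.30) were higher. Vps33a (-1.20 ± 0.32), Gapdhs (-1.05 ± 0.30), Vac14 (-1.01 ± 0.34), Zfp36 (-0.90 ± 0.30) and Pomgnt2 (-0.88 ± 0.28) were lower. None passed (limma, adjusted p = 0.972 for each). The count was 0 at the adjusted threshold and 189 at an unadjusted p below 0.05. By chance 476 would be expected. The count was 287 without Ang1 replicate 1, 567 without Ang1 replicate 3, 118 without VEGF replicate 2, 319 without both libraries that stood apart and 408 with the replicate block. With array weights 24 probe sets passed, 19 higher and 5 lower. By camera 0 of 29 lists were called, with 4 at an unadjusted p below 0.05 and 0 by fry or with an estimated correlation. The shifts were -0.20 for chemokines, -0.10 for cytokines, 0.31 for sprouting genes, 0.19 for proliferation genes and -0.08 for oxidative stress genes (adjusted p = 0.327 for each), 0.24 for interferon genes, 0.29 for endothelial and -0.04 for smooth muscle markers (0.364 for each). They were -0.01 for NF-kB targets (0.763) and 0.17 for macrophage markers (0.769). Without Ang1 replicate 2 calls appeared for chemokines (-0.31), NF-kB targets (-0.28), proliferation (0.20), interferon (0.37) and oxidative stress genes (-0.25), and the oxidative stress shift was 0.04 without Ang1 replicate 3. Without both libraries that stood apart the same 5 lists were called (-0.30, -0.27, 0.20, 0.37 and -0.25), and 0 with an estimated correlation. Without Ang1 replicate 2 the shifts were also 0.14 for sprouting genes, -0.17 for cytokines, 0.03 for endothelial, 0.05 for macrophage and -0.19 for smooth muscle markers. NF-kB targets turned to 0.14 without Ang1 replicate 1, 0.12 without Ang1 replicate 3, 0.04 without VEGF replicate 1 and 0.02 without VEGF replicate 2, and smooth muscle markers to 0.08 without Ang1 replicate 1 and 0.05 without VEGF replicate 3.

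On array B the same comparison placed Dpep2 5.69-fold higher after VEGF (8.20 ± 0.27 against 5.69 ± 0.41 log2 units, SD, n = 3, limma, adjusted p = 0.0839). Afg2b (2.35 ± 0.37 log2, SE), Hars2 (2.28 ± 0.40), Wfdc2 (2.02 ± 0.34) and Smim1 (1.68 ± 0.35) were higher after VEGF. Tesmin (-1.99 ± 0.47), Rundc3a (-1.61 ± 0.31), Tmc4 (-1.60 ± 0.43, with another probe set in the opposite direction), Wbp1l (-1.38 ± 0.36) and Ptges3l (-1.31 ± 0.35) were lower, with adjusted p from 0.0839 to 0.561, so that none passed. The count was 0 at the adjusted threshold and 777 at an unadjusted p below 0.05, 357 higher and 420 lower. By chance 458.3 would be expected. The count was 467 without Ang1 replicate 2, 1569 without Ang1 replicate 3, 391 without VEGF replicate 1, 358 without VEGF replicate 2 and 548 without both libraries that stood apart. With values as deposited 25 probe sets passed, all higher, where the median of all probe sets lay at 0.35. By camera 0 of 14 lists were called, with 2 at an unadjusted p below 0.05 and 0 by fry or with an estimated correlation. Endothelial markers shifted by 0.76 ± 0.52 (7 of 7 higher, adjusted p = 0.186) and were called without VEGF replicate 2 (0.88), but Ang1 replicate 2 had the lowest endothelial mean (-1.64) and without it the shift was 0.18. Chemokines shifted by -0.04 (adjusted p = 0.692), with 1 member, Ccl19, lower past the threshold adjusted over the list alone (-1.10 ± 0.35) and 0 over all genes. Their shift was -0.20 without Ang1 replicate 2 and turned to 0.24 without Ang1 replicate 3 and 0.10 without VEGF replicate 1. Proliferation genes shifted by 0.47 ± 0.12 (adjusted p = 0.186) and were called without Ang1 replicate 2 (0.49) and without both libraries that stood apart (0.49), though not with an estimated correlation.

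Finally, the responses to both factors were set side by side. Both comparisons use the same 3 untreated RNAs, whose chance values enter both. Across 9520 probe sets of array A the log2 differences correlated with r = 0.43, and unchanged groups simulated against the same controls gave 0.50 (SD 0.012, 100 simulations). The covariance was 0.0658 against 0.0884 simulated, and 65.3% of probe sets had the same sign against 66.7% simulated. On array B r was 0.31 against 0.50 (SD 0.0093), the covariance 0.0696 against 0.111 and the same-sign share 60.1% against 66.7%. Leaving out each array in turn moved r between 0.22 and 0.69 on array A and between 0.09 and 0.50 on array B. These simulations drew the groups independently. A second set, added after the result was seen, gave same-numbered arrays the mean correlations of the pairing check (0.40 and 0.29 with untreated for Ang1 and VEGF on array A, 0.20 and 0.22 on array B). Its r was 0.26 (SD 0.012) on array A and 0.35 (SD 0.012) on array B, with covariances of 0.0295 and 0.0623 and same-sign shares of 58.2% and 61.6%. The observed r of array A lay between both simulated values, and that of array B below both. The SE of r from leaving out each array was 0.45 on array A and 0.36 on array B. The simulated SDs do not cover this spread, so the place of r against the simulated values cannot be told. The pairing of the second set is assumed, as the check did not establish it. With the untreated RNAs split 1 against 2, so that each factor had its own controls, r ran from -0.31 to 0.08 on array A and from -0.18 to 0.01 on array B over the 6 arrangements. No split leaves at least 2 RNAs on each side, and part or all of the likeness may come from the shared controls.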

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

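The control probe sets were not part of the comparisons, and each result here was picked because a control signal exceeded 3 times the highest untreated array. All came from Ang1 replicate 2. On array A the ratios were 5.70 for the hybridization control cre, 7.13 for bioB, bioC and bioD, 18.0 for the poly-A control phe, 6.997 for 5S ribosomal RNA, 18.7 for the B1 repeat and 4.86 for the B2 repeat. On array B they were 10.4 for phe, 3.18 for 5S ribosomal RNA, 9.21 for the B1 repeat and 3.83 for the B2 repeat. The rule misses the poly-A control dap, which was high in untreated replicate 2 itself. On array A dap was 348.1 there, 111.2 in Ang1 replicate 1 and 717.3 in VEGF replicate 3, and 0.97 to 7.13 in the others. On array B the same arrays had 1701.5, 481.5 and 2435, and the others 1.97 to 71.7. The poly-A control lys was highest in VEGF replicate 2 and untreated replicate 1, at 77.2 and 44.9 on array A and 267.5 and 170.2 on array B. Elsewhere it was 8.1 to 24.8 on array A and 14.7 to 82.6 on array B. Both groupings cut across the replicate numbers. The cause of these groupings was not tested. The rule for single samples far from their group needs 4 samples, so groups of 3 were not tested by it.

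All tests of explanations in this part were chosen, and some revised, after the results were seen. Only the regroupings of samples were set beforehand. The first pattern weighed was that untreated replicate 2 and Ang1 replicate 2 were low in the same transcripts. A small amount of labelled target would raise the spiked cre signal. In Ang1 replicate 2 cre was at least 4.00 times the median of the other arrays on both array types, in line with little target, and in untreated replicate 2 it was 1.24 times, within the range of 0.618 to 2.18 of the other arrays, which decides nothing. A first version of this test ignored the spread of the other arrays and read that value as excluding the explanation. A shared animal behind replicate number 2 could also be the cause, and as the whole cause it would lower VEGF replicate 2 by a like amount. Over these transcripts, low by at least 2 log2 units in both libraries, VEGF replicate 2 had a median of -0.24 on array A (quartiles -0.60 and 0.13) and -0.36 on array B (-0.84 and 0.25). Medians of VEGF replicates 1 and 3 were 0.07 and 0.13 on array A and 0.005 and 0.44 on array B, so VEGF replicate 2 was the lowest VEGF array. The transcripts were picked as low in the other libraries, which favours a weaker value in VEGF replicate 2. The values argue against a shared animal with an equal effect in each group as the whole cause, and leave a smaller part open. A first version of this test, with a limit of -0.25 on array A alone, had excluded the shared animal, and a second, with that limit on both array types, had left it open.

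The second pattern was the higher chemokine list after both factors on array A. Both shifts are taken against the same untreated RNAs, so chance low values there would raise both, and this was not tested for the list. Without the libraries that stood apart the smaller of the 2 shifts was 0.83 ± 0.079. Both libraries worked against the shifts. Untreated replicate 2 was the untreated array nearest the treated ones, and the VEGF shift rose from 0.57 to 0.81 without it. The Ang1 shift rose from 0.77 to 0.90 without Ang1 replicate 2. Leaving both out could thus only raise the shifts and is no test of what remains. The removal of untreated replicate 2 also narrows the spread, and 2 untreated arrays remain. More macrophages in the treated rings could raise chemokine transcripts. Without both libraries that stood apart the chemokine shift exceeded the macrophage shift by 0.74 ± 0.27 after Ang1 and by 0.39 ± 0.25 after VEGF. More macrophages need not raise both lists by the same amount, and only 2 untreated and 2 Ang1 arrays remained. Neither difference therefore decides this, and it stays open for both factors. The poly-His antibody was given with Ang1 only, so the VEGF shift of 0.57 ± 0.22 cannot come from it, and for the Ang1 shift of 0.77 ± 0.22 it cannot be judged without an antibody-only group.

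The third pattern was the lower smooth muscle list and higher macrophage list after VEGF on array A. A lower share of smooth muscle cells would raise the other cell types alike, and without the libraries that stood apart the macrophage shift exceeded the fibroblast shift by 0.43 ± 0.39, which decides nothing. Untreated replicate 2 had the lowest smooth muscle mean of the untreated arrays and worked against the shift, and Ang1 replicate 2 is in neither group. Leaving both out could thus only deepen the shift, to -0.54 ± 0.14, and is no test of what remains. The remaining shift rests on untreated replicates 1 and 3. Whether high values in those arrays make the shift stays open. An earlier test asked for a high level in single untreated libraries and was read as fitting, with shifts of -0.10 without untreated replicate 1 and -0.07 without untreated replicate 3. It was replaced because both omissions give untreated replicate 2 more weight, and without that replicate the shift was -0.54.

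Regrouping the 6 samples of a comparison gives 10 splits, too few to reach a share under 0.05. For probe sets all 10 splits called at least as many as the real one in each of the 6 comparisons (0), and the highest other count was 0, or 2 for Ang1 on array B. At an unadjusted p below 0.05 the real counts on array A were 157, 302 and 189 for VEGF, Ang1 and VEGF against Ang1, with 724, 1206 and 868 the highest of other splits. On array B they were 66, 960 and 777, with 412, 872 and 1268. Where replicate numbers are taken to pair treated with untreated samples, the real split parts all 3 pairs, as do 3 of the others, and the remaining 6 part 1 pair and keep 2 together. Among the 3 others that part all pairs the highest unadjusted counts were 109 after VEGF and 195 after Ang1 on array A (real 157 and 302), and 117 and 336 on array B (real 66 and 960). The highest list counts among them were 5 and 5 on array A (real 11 and 5) and 0 and 0 on array B, and these 4 splits are also too few for a share under 0.05. For lists after VEGF on array A only 1 split, the real one, called 11, and the highest other called 6. For lists after Ang1 on array A 4 splits called at least the real 5, and the highest other called 11. For VEGF against Ang1 on array A all 10 splits called at least the real 0, and the highest other called 5. On array B this held for 10 splits in each comparison, with 2, 2 and 1 the highest others. In the Ang1 comparison on array A the 4 splits with both libraries that stood apart on 1 side gave 813 to 1206 unadjusted probe sets, and the other 6 gave 113 to 302, and these counts point to a structure of the samples. On array B the ranges overlapped, 521 to 872 for those 4 splits and 172 to 960 for the other 6.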

How the results depend on the processing

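The call stayed on its side of the threshold in 6062 of 6088 alternatives of 281 gene results, though 105 of these values changed sign without a call on either side, and 26 gained a call. Of 3321 alternatives of 129 list results 104 lost a call, 94 gained one and the others kept their side of the threshold. Of the latter 279 changed sign, and 2 more did so from an unadjusted p below 0.05 with no call on either side. Of 288 alternatives of the counts 43 moved. The correlation of both responses ran from 0.22 to 0.69 on array A and from 0.09 to 0.50 on array B with each array left out. The replicate block alone changed no calls but those of proteases after VEGF (adjusted p = 0.0152) and macrophage markers after Ang1 (0.0334) on array A. Where an array was left out, the group of 2 was assumed to vary like the others. Unless stated, the cause of a change was not tested. With 3 samples per group only large changes in single genes could be found.

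With an estimated correlation 0 lists were called after VEGF and 0 after Ang1 on array A, and fry gave 0 and 0. The shifts stay the same by construction in both tests, as only the p-value differs. They were 0.57 for chemokines, 0.45 for NF-kB targets, 0.37 for interferon genes and -0.24 for smooth muscle markers after VEGF, and 0.77 for chemokines and 0.45 for NF-kB targets after Ang1. Without both libraries that stood apart, and so without the untreated array highest in chemokines, 1 list (chemokines) was called after VEGF and 1 after Ang1 with an estimated correlation. NF-kB targets (0.39 after VEGF, 0.67 after Ang1), interferon genes (0.53) and smooth muscle markers (-0.54) were not.

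Without both libraries 8 lists were called after Ang1 and 5 for VEGF against Ang1 on array A, and 3 after VEGF, 3 after Ang1 and 1 for VEGF against Ang1 on array B. With the replicate block added, these were 10 and 2 on array A and 3, 4 and 1 on array B. Then 1 probe set, Ccm2, passed after VEGF and 4 after Ang1 on array A, 3 higher and 1 lower. In this fit replicate number 2 held VEGF replicate 2 alone, which adds nothing to the comparisons once the block is in the model. The comparisons thus rest on replicates 1 and 3, which leaves little to estimate the spread from. With array weights 6 probe sets passed after Ang1 and 24 for VEGF against Ang1 on array A, 2 after Ang1 and 8 for VEGF against Ang1 on array B. Lists called then were 4 for VEGF against Ang1 on array A, and 3 after VEGF and 2 for VEGF against Ang1 on array B.

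With values as deposited 117 probe sets passed after Ang1 and 25 for VEGF against Ang1 on array B, where 1 Ang1 array had been scaled otherwise. Lists called were 7 after VEGF and 2 for VEGF against Ang1 on array A, and 2 for VEGF against Ang1 on array B. After VEGF on array A 7 lists were called with median centring and 7 without a filter. After Ang1 on array A 3 were called with the 60th percentile filter. After VEGF on array B 2 were called with only the compared groups in the model.

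Leaving out each array in turn, lists called ran from 5 to 11 after VEGF, from 4 to 9 after Ang1 and from 0 to 5 for VEGF against Ang1 on array A. On array B they ran from 0 to 3 after VEGF and from 0 to 1 for VEGF against Ang1. On array A the smooth muscle shift after VEGF ran from -0.54 to -0.073 and the interferon shift from 0.10 to 0.57. The macrophage shift after Ang1 ran from -0.022 to 0.43 and turned without untreated replicate 3, and the oxidative stress shift for VEGF against Ang1 ran from -0.25 to 0.038 and turned without Ang1 replicate 3.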

Other observations

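Further gene lists were measured on array A, and none of them was called after VEGF (camera). VEGF early response genes shifted by 0.13 (adjusted p = 0.0799, 20 of 29 higher), with the transcription factor gene Egr1 at 0.54 ± 0.28 and the growth factor gene Hbegf at 0.63 ± 0.34 (SE, n = 3 per group) and the calcineurin regulator gene Rcan2 at -1.08 ± 0.51, and they were called without VEGF replicate 3 (0.17). Dendritic markers shifted by 0.33 (0.101), share 3 of 5 genes with the MHC class II list, and were called without untreated replicate 2 (0.47) or VEGF replicate 2 (0.44), and without both libraries that stood apart (0.50, but adjusted p = 0.291 with an estimated correlation). The shifts were 0.24 for leukocyte adhesion (0.299), 0.12 for angiogenic ligands and receptors (0.339), 0.14 for structural matrix (0.499; -0.03 with median centring), 0.17 for oxidative stress (0.465) and 0.16 for heat shock genes (0.662), where the crystallin gene Cryab was lower (-0.95 ± 0.38). Notch genes shifted by 0.07 (0.687), cholesterol synthesis genes by 0.09 (0.299) and pericyte markers by 0.07 (0.858), all with medians below 0. Near 0 lay FOXO targets at -0.02 (0.854; 0.06 with values as deposited), proliferation at -0.02 (0.824; 0.08 with values as deposited), fibroblast markers at 0.09 (0.462; -0.06 with median centring) and adipocyte markers at -0.02 with a median of 0.01 (0.954; 0.11 with values as deposited). Schwann cell markers shifted by -0.10 (0.454). Ribosomal protein genes shifted by -0.001 (0.454) and were called with values as deposited (-0.16) or median centring (-0.26), and without both libraries that stood apart (-0.12, but adjusted p = 0.283 with an estimated correlation). Without untreated replicate 2 the shifts were 0.11 for leukocyte adhesion, 0.05 for angiogenic, 0.01 for matrix, 0.01 for oxidative stress, 0.03 for heat shock and -0.13 for ribosomal genes. They turned to -0.003 for cholesterol synthesis, -0.06 for pericyte, 0.12 for adipocyte, 0.04 for Schwann cell and 0.01 for proliferation genes. Other single arrays turned the smallest shifts. Without VEGF replicate 3 they were -0.06 for fibroblast, 0.06 for FOXO, -0.01 for pericyte and 0.01 for proliferation genes, and without VEGF replicate 2 the adipocyte shift was 0.05. Without untreated replicate 1 the proliferation shift was 0.02 and the ribosomal shift 0.05, and the latter was 0.08 without untreated replicate 3, 0.003 without Ang1 replicate 2 and 0.01 without VEGF replicate 1.

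After Ang1 a number of lists stayed below the threshold on array A. Notch genes shifted by 0.23 (adjusted p = 0.0932), with Dtx1 at 1.00 ± 0.51, and were called without Ang1 replicate 3 (0.35), with values as deposited (0.45) and with median centring (0.31). Complement genes shifted by 0.22 (0.171), hypoxia genes by 0.08 (0.215; -0.03 with median centring) and ER stress genes by 0.07 (0.412; -0.05 with median centring), and each was called without Ang1 replicate 2 (0.44, 0.28 and 0.36), and hypoxia genes also without both libraries that stood apart (0.24, but adjusted p = 0.405 with an estimated correlation). Structural matrix genes shifted by -0.13 (0.685) and were called with values as deposited (-0.21) and with median centring (-0.35). The shifts were 0.27 for dendritic markers (0.212), 0.10 for proteases (0.738), 0.09 for leukocyte adhesion (0.605), 0.05 for fibroblast markers (0.605), 0.04 for heat shock genes (0.868) and 0.01 for sprouting genes (0.868), and with median centring these last 5 turned to -0.12, -0.01, -0.11, -0.09 and -0.20. They were -0.11 for cholesterol synthesis (0.887; 0.08 with values as deposited), -0.12 for pericyte markers (0.705; 0.02 with values as deposited) and -0.08 for ribosomal protein genes (0.788). Mean and median differed in sign for angiogenic genes (-0.01 and 0.08; 0.724), early response genes (-0.0005 and 0.11; 0.605), FOXO targets (0.06 and -0.03; 0.605), adipocyte markers (0.02 and -0.03; 0.868) and Schwann cell markers (0.04 and -0.04; 0.868), and camera ranked the first 2 of these as higher. With values as deposited angiogenic genes turned to 0.13 and early response genes to 0.15, and with median centring Schwann cell markers turned to -0.04. Single arrays moved most of these shifts. Without Ang1 replicate 2 they were 0.12 for Notch, 0.03 for dendritic, 0.34 for protease, 0.32 for leukocyte adhesion, 0.20 for heat shock, 0.19 for sprouting, 0.17 for FOXO and -0.05 for pericyte genes. They turned to 0.16 for cholesterol synthesis, 0.09 for matrix, 0.09 for angiogenic, 0.12 for early response and -0.19 for Schwann cell genes. Without untreated replicate 2 they were 0.04 for complement, 0.42 for dendritic, -0.20 for cholesterol synthesis, -0.26 for matrix, -0.25 for pericyte, -0.21 for ribosomal, 0.15 for adipocyte and 0.18 for Schwann cell genes. They turned to -0.13 for ER stress, -0.02 for fibroblast, -0.09 for heat shock, -0.04 for leukocyte adhesion, -0.01 for protease and -0.08 for sprouting genes. Without untreated replicate 3 the shifts turned to -0.01 for dendritic, -0.12 for adipocyte, -0.15 for Schwann cell, 0.05 for angiogenic and 0.001 for ribosomal genes, and without untreated replicate 1 to 0.07 for early response genes. Without Ang1 replicate 1 they turned to -0.07 for ER stress, -0.06 for heat shock, -0.03 for FOXO, -0.01 for leukocyte adhesion and -0.003 for sprouting genes. Without Ang1 replicate 3 they turned to -0.06 for ER stress, -0.01 for heat shock, -0.05 for hypoxia, -0.05 for leukocyte adhesion, -0.07 for protease, -0.15 for sprouting and -0.19 for adipocyte genes.

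Between VEGF and Ang1 on array A the remaining shifts were -0.17 for Notch genes (adjusted p = 0.327), 0.27 for structural matrix (0.364), 0.21 for ER stress (0.364), 0.19 for cholesterol synthesis (0.381) and 0.16 for proteases (0.381). They were -0.08 for FOXO targets (0.453), -0.14 for Schwann cell markers (0.488), 0.13 for early response genes (0.546), 0.20 for complement (0.597), 0.19 for pericyte markers (0.597), 0.13 for hypoxia genes (0.769) and 0.15 for leukocyte adhesion (0.886). Mean and median differed in sign for angiogenic genes (0.14; 0.816), MHC class II (-0.01 and 0.18; 0.857; mean 0.05 with median centring), heat shock genes (0.12 and -0.03; 0.962) and adipocyte markers (-0.03 and 0.03; 0.886). Camera ranked ribosomal (0.08; 0.816) and fibroblast genes (0.04; 0.962) as lower although their means were above 0, and with values as deposited the ribosomal mean turned to -0.03. Dendritic markers shifted by 0.05 (0.962). Leaving out Ang1 replicate 2 moved most of these shifts. Without it they turned to -0.07 for ER stress, -0.07 for cholesterol synthesis, -0.08 for protease, -0.01 for complement, -0.07 for hypoxia, -0.08 for leukocyte adhesion, -0.03 for heat shock, 0.08 for Schwann cell and 0.18 for MHC class II genes. The shifts were then 0.05 for matrix, -0.05 for Notch, 0.01 for early response, 0.03 for angiogenic, -0.19 for FOXO and 0.31 for dendritic genes. Without Ang1 replicate 1 dendritic (-0.02), fibroblast (-0.01) and FOXO genes (0.01) turned, and without Ang1 replicate 3 adipocyte (0.17) and dendritic genes (-0.11). Without VEGF replicate 1 dendritic genes (-0.09) turned, without VEGF replicate 2 adipocyte (0.04) and MHC class II genes (0.08), and without VEGF replicate 3 fibroblast (-0.12), heat shock (-0.01) and MHC class II genes (0.01).

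On array B the other lists after VEGF shifted by 0.20 for interferon (adjusted p = 0.558), and with 0.601 for each by 0.18 for NF-kB targets, 0.19 for sprouting, 0.10 for proliferation, 0.14 for endothelial, -0.06 for matrix and -0.18 for FOXO genes. Notch genes shifted by 0.04 (0.714; -0.06 with median centring), angiogenic genes by 0.08 (0.813) and proteases by 0.13 (0.813). Without untreated replicate 2 the shifts were 0.49 for interferon (called), 0.01 for sprouting and -0.12 for matrix genes, and they turned to -0.21 for angiogenic, -0.07 for protease, -0.02 for Notch, -0.06 for endothelial and 0.01 for FOXO genes. Without untreated replicate 3 interferon (-0.17), matrix (0.06) and proliferation genes (-0.02) turned, without VEGF replicate 1 matrix genes (0.01), and without VEGF replicate 3 angiogenic (-0.13), FOXO (0.02) and Notch genes (-0.16).

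After Ang1 on array B NF-kB targets shifted by 0.28 (adjusted p = 0.579; 0.57 and called without both libraries, but adjusted p = 0.664 with an estimated correlation) and Notch genes by -0.08 (0.821). With 0.80 for each, the shifts were -0.23 for angiogenic, -0.32 for FOXO, -0.22 for protease, -0.23 for interferon and -0.16 for smooth muscle genes, 0.07 for macrophage markers (-0.67 with values as deposited, 0.41 and called without both libraries that stood apart, but adjusted p = 0.683 with an estimated correlation), 0.02 with a median of -0.02 for sprouting genes (-0.45 with values as deposited), and -0.19 for early response genes, which camera ranked as higher. Without Ang1 replicate 2 the shifts were -0.02 for angiogenic, 0.38 for macrophage, 0.52 for NF-kB and 0.30 for sprouting genes, and they turned to 0.18 for protease, 0.12 for early response and 0.07 for Notch genes. Without untreated replicate 2 they were -0.52 for angiogenic, -0.12 for FOXO, -0.13 for Notch, -0.41 for protease, -0.09 for smooth muscle, 0.11 for macrophage and -0.28 for early response genes, and turned to 0.08 for interferon and -0.15 for sprouting genes. Without untreated replicate 3 angiogenic (0.05) and macrophage genes (-0.13) turned, without Ang1 replicate 1 macrophage (-0.09) and sprouting genes (-0.02), and without Ang1 replicate 3 macrophage (-0.06), NF-kB (-0.12) and sprouting genes (-0.19).

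Between VEGF and Ang1 on array B, with an adjusted p of 0.692 for each, the shifts were 0.31 for angiogenic, 0.59 for early response, 0.20 for matrix, 0.43 for interferon and -0.09 for smooth muscle genes (0.43 with values as deposited), and -0.10 with a median of 0.11 for NF-kB targets (0.21 with values as deposited). Notch (0.12) and protease genes (0.35) had 0.796 and macrophage markers (0.25) 0.873. FOXO targets (0.14) and sprouting genes (0.17, ranked as lower by camera) had 0.913. Without Ang1 replicate 2 the shifts were 0.30 for early response, 0.10 for angiogenic and -0.33 for NF-kB genes, and they turned to -0.04 for protease, -0.02 for Notch, -0.04 for macrophage and -0.10 for sprouting genes. NF-kB genes turned to 0.30 without Ang1 replicate 3, and Notch (-0.08) and sprouting genes (-0.02) turned without VEGF replicate 3.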
